A study of Homo sapiens with 3 samples.

How the data were processed

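mRNA was measured by RNA sequencing in HCC827, an established human lung adenocarcinoma cell line with an activating EGFR mutation. The series held 3 libraries, 1 from DMSO vehicle, 1 from compound 1 and 1 from compound 2, and the labels gave both compounds at 5 μM for 24 h. They gave no time for the DMSO library. Per the labels' protocols, RNA was taken with Trizol and libraries were built with an Illumina TruSeq RNA kit; whether the kit marked strand was not stated. Bowtie 0.12.2 and the genome builds GRCh38.p12 (human) and mm8 (mouse) were listed, per the submitters' processing notes, which gave neither a role nor an order for them. The gene annotation and the counting step were not given in the sources used here.

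The authors deposited 1 table with a value per gene and library under column headers that named FPKM. Each column of the deposited table summed to 1000000, so the values were on the TPM scale and were treated and named as TPM throughout. TPM is a share of the summed length-corrected signal, so a few highly expressed genes that gain share lower the value of every other gene in that library. The table listed 20332 genes, 617 of them without a symbol, and 4883 of them were at 0 in all 3 libraries. No read counts were used here. Of the gene identifiers, 20113 were in GENCODE 29 on GRCh38, which supplied the coordinates, transcript lengths and GC contents given here, and 219 were not. The longest transcript of each gene stood for its length and GC content.

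Depth was estimated from low values, because a gene's TPM moves in steps of what 1 read is worth. One read per kb of transcript was worth about 0.114 TPM in the DMSO library, 0.106 in the compound 1 library and 0.123 in the compound 2 library. With these steps, between 56.4% and 58.2% of the values of low genes with a single annotated transcript came within 0.1 of a whole number of reads. The steps were fitted to these same values, which raises that share, so it does not test them. At 5 TPM a 2-kb transcript would then rest on about 87.7, 93.9 and 81.3 reads in the DMSO, compound 1 and compound 2 libraries. These estimates assume the GENCODE lengths and are approximate.

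Gene ratios were computed as the log2 ratio of TPM + 1 between 2 libraries, for the 11600 genes with a mean of at least 1 TPM over the 3 libraries. The pseudocount of 1 makes the ratios of low genes smaller than their true fold. With 1 library per group there is no replicate error, so no p-value, standard deviation or interval was computed for any gene or list, and genes past 2-fold were counted without a test. Comparisons were compound 1 against DMSO, compound 2 against DMSO, and compound 2 against compound 1. For 39 gene lists, the median log2 ratio of the members measured at the mean of 1 TPM was set against 10000 random lists of the same size, matched in 20 bins of mean TPM. A median below percentile 2.5 or above percentile 97.5 was called outside the random lists, as a description of these libraries. Lists with fewer than 3 measured members were left out of that step, which left 37. Some genes were in 2 lists, such as SLC7A11, CCND1 and DDB2.

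Both comparisons with DMSO used the same DMSO library. Chance values of their overlap and correlation came from 100 simulated pairs of unchanged libraries, each pair set against a simulated control. Noise for every simulated library was drawn from the difference between the compound 1 and compound 2 libraries. The measured DMSO library did not enter, and equal noise with a shared control fixes the simulated correlation near 0.5. The difference between the compound libraries holds both noise and any real difference between the compounds, and a single pair of libraries cannot separate them.

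Genes to be named were chosen by rule. For each comparison these were the 12 genes with the largest and the 12 with the smallest log2 ratio among genes with a symbol and at least 5 TPM in at least 1 of the 2 libraries, leaving out XIST and Y-linked genes. For each described list they were up to 4 members with the largest absolute log2 ratio and any other member past 2-fold. ATR, ATRIP, CHEK1, TOPBP1 and EGFR were given in every library. The gene lists, the naming rule, the threshold, the pseudocount and 12 alternative settings were chosen before the data were examined, when the unit was taken to be FPKM. One further alternative, in which the medians of bins of transcript length and then of GC content were subtracted from the log2 ratios, was added after seeing the data. So was the protease list without its members at 0 in the DMSO library. Sequence shared between genes was measured on the longest GENCODE transcript of each listed gene. It was the percentage of a gene's 31-mers that also occur in any other gene, since reads from such stretches cannot be assigned to 1 gene. The closest gene is the one that shares the most 31-mers.

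The computation was tested on simulated data for compound 1 against DMSO over 11600 genes, in which 97% of the genes given a log2 change of 2 and 91% of those given 1.5 came out past 2-fold, 49 unchanged genes did so too, and 4% of 200 unchanged lists were called outside the random lists. The simulated noise was drawn independently for each gene, with its spread taken from the difference between the compound libraries. It held no noise particular to the DMSO library and no length or GC trend, and the unchanged lists were random genes. These values therefore check the computation and are not error rates for the measured comparisons. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.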

Results

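The series asked how the transcriptome of HCC827 cells responds to a pair of compounds that the title describes as daphnane diterpenoids, a class of plant-derived molecules, and links to the DNA damage response that ATR controls. ATR is the kinase that senses stalled replication forks and activates CHK1. Each of the 3 libraries, DMSO, compound 1 and compound 2, was the only one of its group. No value below therefore has a replicate error, and each difference is a difference between 2 libraries. Between 14154 and 14473 genes were above 0 in a library, and between 11481 and 11518 reached 1 TPM. The 10 most abundant genes took 8.68% of the signal in the DMSO library, 9.22% after compound 1 and 8.62% after compound 2. GAPDH was the most abundant gene in the DMSO library (16988 TPM) and after compound 2 (12233 TPM), and FTH1, the ferritin heavy chain, after compound 1 (15730 TPM). The 13 mitochondrially encoded genes took 4.24% of the signal in the DMSO library, 2.00% after compound 1 and 2.74% after compound 2.

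The first comparison asked what compound 1 does to HCC827 cells. After compound 1, genes of DNA replication and mitosis were lower, while most NF-kB target and cytokine genes and 10 of 19 genes of the integrated stress response were at least 2-fold higher. MMP1, the interstitial collagenase (ENSG00000196611, chromosome 11, 102789920 to 102798160), was at 9.04 TPM in the DMSO library and 1893 TPM after compound 1, a log2 ratio of 7.56. IL1A, which encodes interleukin 1 alpha (ENSG00000115008, chromosome 2, 112773915 to 112784590), was at 5.79 and 197 TPM (log2 ratio 4.87). CDKN1A, the p21 inhibitor of cyclin-dependent kinases (ENSG00000124762, chromosome 6, 36676460 to 36687339), was at 23.2 and 349 TPM (log2 ratio 3.85). GINS2, a subunit of the replicative helicase (ENSG00000131153, chromosome 16, 85676198 to 85690073), was at 41.4 and 3.15 TPM (log2 ratio -3.35).

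Of 11600 genes, 1707 were at least 2-fold higher and 939 at least 2-fold lower after compound 1, so 64.5% of the genes past 2-fold were higher. The median log2 ratio of all genes was 0.11. Median-of-ratios scaling brought the median to 0.01 and the higher share to 56.0%, and upper-quartile scaling to 0.02 and 56.9%. With the trend in transcript length and GC content subtracted, 976 genes were higher and 1042 lower, a higher share of 48.4%. The excess of higher genes was thus smaller under the other scalings. The subtraction sets the median to 0 by construction, so the last split does not show that the excess is absent. Across 11542 genes, which are not independent, the Spearman correlation of the log2 ratio with transcript length was 0.30, and with GC content -0.39. The median log2 ratio was -0.18 in the shortest 25% of transcripts, up to 2378 bases, and 0.48 in the longest 25%, from 5412 bases.

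Among genes above 0 in the DMSO library, the largest log2 ratios after MMP1 belonged to AKR1C2 (5.59) and AKR1C1 (4.17), which encode aldo-keto reductases, IL1A, PTGS2 (4.65), TRAF1 (4.63), the cystine transporter gene SLC7A11 (4.51), the decoy receptor gene IL13RA2 (4.38), LURAP1L (4.32) and SERPINB7 (4.13). AKR1C1 and AKR1C2 share sequence, with 35.4% of the 31-mers of AKR1C1 and 63.5% of those of AKR1C2 also found in other genes. Each was the closest gene to the other, so their split is uncertain. MMP10, which encodes stromelysin-2, was listed at 0 in the DMSO library and at 98.4 TPM after compound 1. DEFB103A, a beta-defensin gene whose 31-mers all occur in other genes, with DEFB103B the closest, was listed at 0 and at 52.2 TPM. At the other end stood FGB, the fibrinogen beta chain gene (ENSG00000171564, chromosome 4, 154562956 to 154571086), at 141 TPM in the DMSO library and 1.65 TPM after compound 1 (log2 ratio -5.75). It was followed by ERP27 (-4.74), the gap junction gene GJB1 (-4.54), EPN3 (-4.25), SERPINA6, which encodes corticosteroid-binding globulin (-3.84), MYBL2, a transcription factor gene of the cell cycle (-3.73), the glutathione peroxidase gene GPX2 (-3.68), OLFM4 (-3.60), LY6D (-3.55), P2RY6 (-3.54) and the mucin gene MUC5B (-3.53).

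All 34 measured genes of the DNA replication list were at least 2-fold lower after compound 1, with a median log2 ratio of -2.0. Among them were TK1 (-2.84), TYMS (-2.76) and RRM2 (-2.74), which encode enzymes of nucleotide synthesis. Of 26 mitosis and G2-M genes, 25 were at least 2-fold lower and none higher (median -2.17). BIRC5, which encodes survivin, was at -2.85, KIF20A at -2.81, and the mitotic kinase genes AURKB and PLK1 at -2.77 and -2.68. The G1-S regulators were divided, with 8 of 18 lower and 4 higher (median -0.41). E2F1 (-2.26), E2F8 (-2.09) and CCNE2 (-2.05) were lower, and CDKN2B, which encodes the p15 inhibitor, was higher (2.11). The replication, mitosis and G1-S medians lay below the random lists, and the G1-S median lay inside them at a mean of at least 5 TPM or without its member of largest ratio (-0.26 in both).

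For the pathway named in the series title, ATR itself (ENSG00000175054, chromosome 3, 142449235 to 142578826) was at 10.3 TPM in the DMSO library and 15.5 TPM after compound 1 (log2 ratio 0.55). ATRIP, its binding partner (ENSG00000164053, chromosome 3, 48446710 to 48467645), was at 13.7 and 4.05 TPM (-1.54). ATRIP overlaps TREX1 on the genome, and 31.1% of its 31-mers also occur in other genes, with TREX1 the closest. TREX1 was at 10.8 and 5.44 TPM. CHEK1, which encodes CHK1 (ENSG00000149554, chromosome 11, 125625136 to 125676255), was at 48.7 and 27.8 TPM (-0.79), and the ATR activator gene TOPBP1 (ENSG00000163781, chromosome 3, 133598175 to 133662380) at 28.4 and 19.9 TPM (-0.49). Over the ATR-CHK1 checkpoint list 6 of 18 genes were at least 2-fold lower and none higher (median -0.75, below the random lists). The 6 were CDC25A (-1.93), CDC25C (-1.91), ATRIP, CLSPN (-1.52), RPA1 (-1.34) and TIMELESS. The random lists were matched on mean TPM only. For this list and the repair lists, after either compound, a median below them is therefore not separated from the wider fall of replication and mitosis genes.

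Repair lists differed from one another. In homologous recombination 9 of 17 genes were at least 2-fold lower (median -1.02), among them EXO1 (-2.64), XRCC3 (-2.36) and RAD54L (-2.19). In the Fanconi anaemia pathway 7 of 15 were lower (median -0.85), with UBE2T at -2.24 and FANCA at -2.22. In base excision and mismatch repair 4 of 15 were lower (median -0.59), with NEIL3 at -2.46 and UNG at -2.26. None of these 3 lists had a member 2-fold higher, and all 3 medians lay below the random lists. Double-strand break sensing and end joining had 3 of 16 genes higher and 3 lower (median 0.07, inside the random lists). There the DNA ligase IV gene LIG4 (1.94), RAD50 (1.39) and ATM (1.11) were higher, and H2AX (-2.22), CHEK2 (-1.23) and MDC1 (-1.14) lower. Nucleotide excision repair had 1 gene higher (ERCC4, 1.37) and 1 lower (DDB2, -1.23) of 14 (median 0.11, inside).

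Of 21 NF-kB targets and inflammatory cytokines 17 were at least 2-fold higher (median 2.03), including IL1A, PTGS2, TRAF1 and the neutrophil chemokine gene CXCL8 (3.88), while CXCL1 was lower (-1.82). Of 11 genes for proteases and the plasminogen system 6 were higher and 2 lower (median 1.97). The urokinase gene PLAU was at 642 and 2512 TPM (1.97) and MMP7 at 71.5 and 7.50 TPM (-3.09). MMP10, MMP9 and SERPINB2 were listed at 0 in the DMSO library, and without them the median was 0.72, still above the random lists at percentile 98.1. With no filter on low values the list median was 0.40, also above. The MAPK feedback genes had 9 of 15 higher and none lower (median 1.11), led by the phosphatase gene DUSP5 (3.11). The immediate early and AP-1 list had 6 of 16 higher and none lower (median 0.81), led by KLF6 (3.09) and ATF3 (3.05). In the ERBB and MET list 5 of 12 were higher and none lower (median 0.95), with HBEGF at 2.11 and EREG at 2.07. EGFR, the mutated driver of this line (ENSG00000146648, chromosome 7, 55019021 to 55211628), was at 680 TPM in the DMSO library and 1579 TPM after compound 1 (1.21, and 0.60 with the length and GC trend subtracted). All 5 medians lay above the random lists. The protein kinase C list, which also held PRKD and RASGRP genes, had 2 of 9 higher. They were PRKCI (1.46) and RASGRP3 (1.87), which is not a protein kinase C gene. The list median of 0.47 lay inside the random lists, but above with the trend subtracted (0.57). Interferon-stimulated genes had 8 of 25 higher and 1 lower (median 0.56, above), with IFI44L at 2.60 and ISG20 at 2.38.

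Medians of the integrated stress response, unfolded protein response, NRF2 target and autophagy lists were also higher. The integrated stress response had 10 of 19 genes at least 2-fold higher (median 1.39), with SLC7A11, CTH (3.63), CHAC1 (2.76) and the asparagine synthetase gene ASNS (2.71), and ATF5 lower (-1.32). Of 17 unfolded protein response genes 7 were higher and 1 lower (median 0.94), led by DNAJB9 (3.50) and HERPUD1 (2.25). Of 20 NRF2 targets 10 were higher and 2 lower (median 0.95), with HMOX1 at 2.36 and AKR1B10 at -1.25. Of 18 genes for autophagy and the lysosome 9 were higher and none lower (median 0.97), with the cathepsin L gene CTSL at 3.05 and SQSTM1 at 2.75. The replication-dependent histone list had 5 of 8 higher (median 1.25), with H2BC4 at 2.33. These 5 medians lay above the random lists. Of 23 p53 targets 8 were higher and 1 lower, with CDKN1A, SESN2 (3.74), PLK3 (2.34) and BBC3 (2.26) in front, and the list median was 0.39, inside the random lists, but above with the length and GC trend subtracted (0.51). Apoptosis regulators had 5 of 20 higher and 1 lower (median 0.58, above), with XIAP at 2.5 and the pro-death gene BIK at 2.10, and lay inside at a pseudocount of 5 (0.44). Heat shock proteins had none of 13 higher and HSPE1 (-1.21) lower (median -0.42, just below, and inside the random lists under 5 of the other settings).

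The mitochondrially encoded list had 10 of 13 genes at least 2-fold lower (median -1.12), with MT-CYB at -1.48. Nuclear genes of oxidative phosphorylation had 1 of 27 past 2-fold, NDUFA9 at -1.04 (median -0.54). Of 25 genes for glycolysis and hypoxia 11 were lower and 1 higher (median -0.85), with ALDOC at -1.84, PGAM1 at -1.27 and NDRG1 at 1.60. These 3 medians lay below the random lists. Cholesterol synthesis had 2 of 22 lower, with a median of -0.30. Fatty acid synthesis had 1 of 12 higher, ACSL4 (1.06), with a median of -0.19. Both lay inside, and the cholesterol median lay below under 3 of the other settings. Ribosome biogenesis had FBL (-1.33) and NME1 (-1.17) lower of 22 (median -0.28, inside, but below with the trend subtracted, -0.31), and none of 29 cytosolic ribosomal protein genes passed 2-fold (median -0.07, inside). Common reference genes were not level, with TUBA1B (-1.88), TUBB (-1.63) and PGK1 (-1.23) lower and YWHAZ (1.40) higher of 15 (median -0.60, below the random lists).

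Lineage genes differed in both directions. Among 18 epithelial genes 4 were higher and 4 lower (median 0.04, inside), with the keratin gene KRT8 at -1.75 and the tight-junction genes OCLN and TJP1 at 1.65 and 1.45. Among 14 mesenchymal genes 3 were higher and 2 lower (median 0.25, inside, but above with the length and GC trend subtracted, 0.47), with VIM at 2.32, ZEB1 at 2.01 and TGFBI at -1.89. The lung list had 1 higher and 3 lower of 7 (median -0.36, inside, but below at a mean of at least 5 TPM, -1.10, and with no filter on low values, -0.29). Its members included MUC5B, ABCA3 (2.04), the napsin gene NAPSA (-1.63) and NKX2-1 (-1.10). Squamous differentiation had 4 of 10 higher and 5 lower (median -0.75, below, but inside at a mean of at least 5 TPM, 0.08, with no filter, -0.21, and with the trend subtracted, -0.27), with SPRR1B at 2.86 and the calprotectin gene S100A9 at -2.46. Of the other cell types, fibroblast markers had 2 of 9 genes measured, ACTA2 at 1.92 TPM in the DMSO library and COL1A1 at 1.90 TPM, and no endothelial marker was measured. Leukocyte markers had 3 of 12 measured, among them CD68, a lysosomal protein gene that many cell types express, at 243 and 421 TPM, and HLA-DRA at 8.07 and 0.796 TPM. Their median was -0.19, inside. In all, 25 of 37 lists lay outside the random lists.

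The second comparison asked the same of compound 2 at the same dose and time. After compound 2, replication and mitosis genes were again lower, and most NF-kB target and cytokine genes and 8 of 19 genes of the integrated stress response were at least 2-fold higher. MMP1 was at 1852 TPM (log2 ratio 7.53), IL1A at 493 TPM (6.18), CXCL8 at 733 TPM against 26.9 TPM in the DMSO library (4.72), and CDKN1A at 328 TPM (3.77). FGB was at 1.82 TPM (-5.66) and GINS2 at 6.68 TPM (-2.46). Of 11600 genes, 1467 were at least 2-fold higher and 761 lower, a higher share of 65.8%, with a median log2 ratio of 0.09. Upper-quartile scaling gave 1173 higher and 969 lower (54.8%, median -0.02), and subtracting the length and GC trend gave 790 and 865 (47.7%).

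Among genes above 0 in the DMSO library, the others with the largest ratios were TRAF1 (5.93), SERPINB7 (4.87), the activin subunit gene INHBA (4.78), the interleukin gene IL23A (4.62), ESM1 (4.44) and MAST4 (4.30). MMP10, MMP9 and DEFB103A, listed at 0 in the DMSO library, were at 78.1, 19.8 and 20.7 TPM. The lowest after FGB were GPX2 (-4.73), GJB1 (-4.69), ERP27 (-4.39), EPN3 (-4.20), LY6D (-4.00), OLFM4 (-3.97), the fibrinogen gamma chain gene FGG (-3.96), SERPINA6 (-3.76), MUC5B (-3.65), the osteopontin gene SPP1 (-3.61) and CFI (-3.55). The value of CFI is uncertain, since 50.2% of its 31-mers occur in other genes.

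After compound 2, ATR was at 16.0 TPM (0.59), ATRIP at 4.10 TPM (-1.53), with TREX1 at 5.06 TPM, CHEK1 at 31.6 TPM (-0.61), TOPBP1 at 23.6 TPM (-0.26) and EGFR at 1685 TPM (1.31, and 0.72 with the length and GC trend subtracted). In the DNA replication list 30 of 34 genes were at least 2-fold lower (median -1.49), and in mitosis and G2-M 23 of 26 (median -1.5), with TK1 at -2.19 and KIF20A at -2.27. Lists below the random lists also included the ATR-CHK1 checkpoint (5 of 18 lower, median -0.58), homologous recombination (7 of 17, -0.82), the Fanconi anaemia pathway (5 of 15, -0.67) and base excision and mismatch repair (2 of 15, -0.57). None of these 6 lists had a member 2-fold higher. Double-strand break sensing (3 higher and 2 lower of 16, median 0.10), nucleotide excision repair (1 higher of 14, 0.15) and G1-S regulators (5 higher and 6 lower of 18, -0.04) lay inside the random lists.

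Of the NF-kB and cytokine list 20 of 21 genes were at least 2-fold higher and none lower after compound 2 (median 2.27). The protease and plasminogen list had 7 of 11 higher and 1 lower (median 1.92, 0.82 without the 3 genes listed at 0, and 0.45 with no filter, all above). MAPK feedback genes had 7 of 15 higher and 1 lower (0.89), immediate early genes 6 of 16 higher (0.76, and 0.39 at a pseudocount of 5), and the ERBB and MET list 5 of 12 higher (0.68). The integrated stress response had 8 of 19 higher and 1 lower (0.69), with SLC7A11 at 3.46 and CTH at 2.81. NRF2 targets had 7 of 20 higher and 2 lower (0.52), autophagy and lysosome 7 of 18 higher (0.85), the unfolded protein response 5 of 17 higher (0.60), and histones 4 of 8 higher (0.77). These 10 medians lay above the random lists. The ERBB and MET and the unfolded protein response medians lay inside with the length and GC trend subtracted (0.43 and 0.39), the latter also without its member of largest ratio (0.47). The histone median lay inside at a pseudocount of 5 (0.49), with no filter on low values (0.23) and without H2BC21, its member of largest ratio (0.25).

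The p53 targets had 8 of 23 higher and none lower (median 0.48, inside at percentile 97.3, and above under 5 of the other settings). Apoptosis regulators (6 higher and 1 lower of 20, median 0.27), interferon-stimulated genes (9 higher and 1 lower of 25, 0.37), the protein kinase C list (2 higher of 9, 0.43) and heat shock proteins (none past 2-fold of 13, -0.13) lay inside. The interferon median lay above with the length and GC trend subtracted (0.62). Mitochondrially encoded genes had none of 13 past 2-fold (median -0.57), nuclear oxidative phosphorylation genes 1 of 27 lower (-0.46), glycolysis and hypoxia 7 of 25 lower (-0.82), cholesterol synthesis 4 of 22 lower (-0.39), with MVK at -1.5, and fatty acid synthesis 1 of 12 lower and 1 higher (-0.45), with SCD at -1.13. These 5 lay below the random lists, as did common reference genes (3 lower and 1 higher of 15, -0.38), squamous differentiation (6 lower and 4 higher of 10, -1.76, but -0.50 at a mean of at least 5 TPM and -0.28 with no filter, both below) and the 3 leukocyte markers (2 lower, -1.4). The leukocyte median lay inside at a pseudocount of 5 (-0.43) and without its member of largest ratio (-0.28). Epithelial (4 lower and 2 higher of 18, -0.08), mesenchymal (3 higher and 2 lower of 14, 0.39) and lung lineage genes (3 lower and 1 higher of 7, -0.42), ribosome biogenesis (1 higher of 22, -0.08) and cytosolic ribosomal proteins (none past 2-fold of 29, -0.16) lay inside. The lung median lay below at a mean of at least 5 TPM (-1.65) and with no filter on low values (-0.30). The mesenchymal median lay above with no filter (0.38) and with the trend subtracted (0.53). In all, 24 of 37 lists lay outside.

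**Figure D1:**
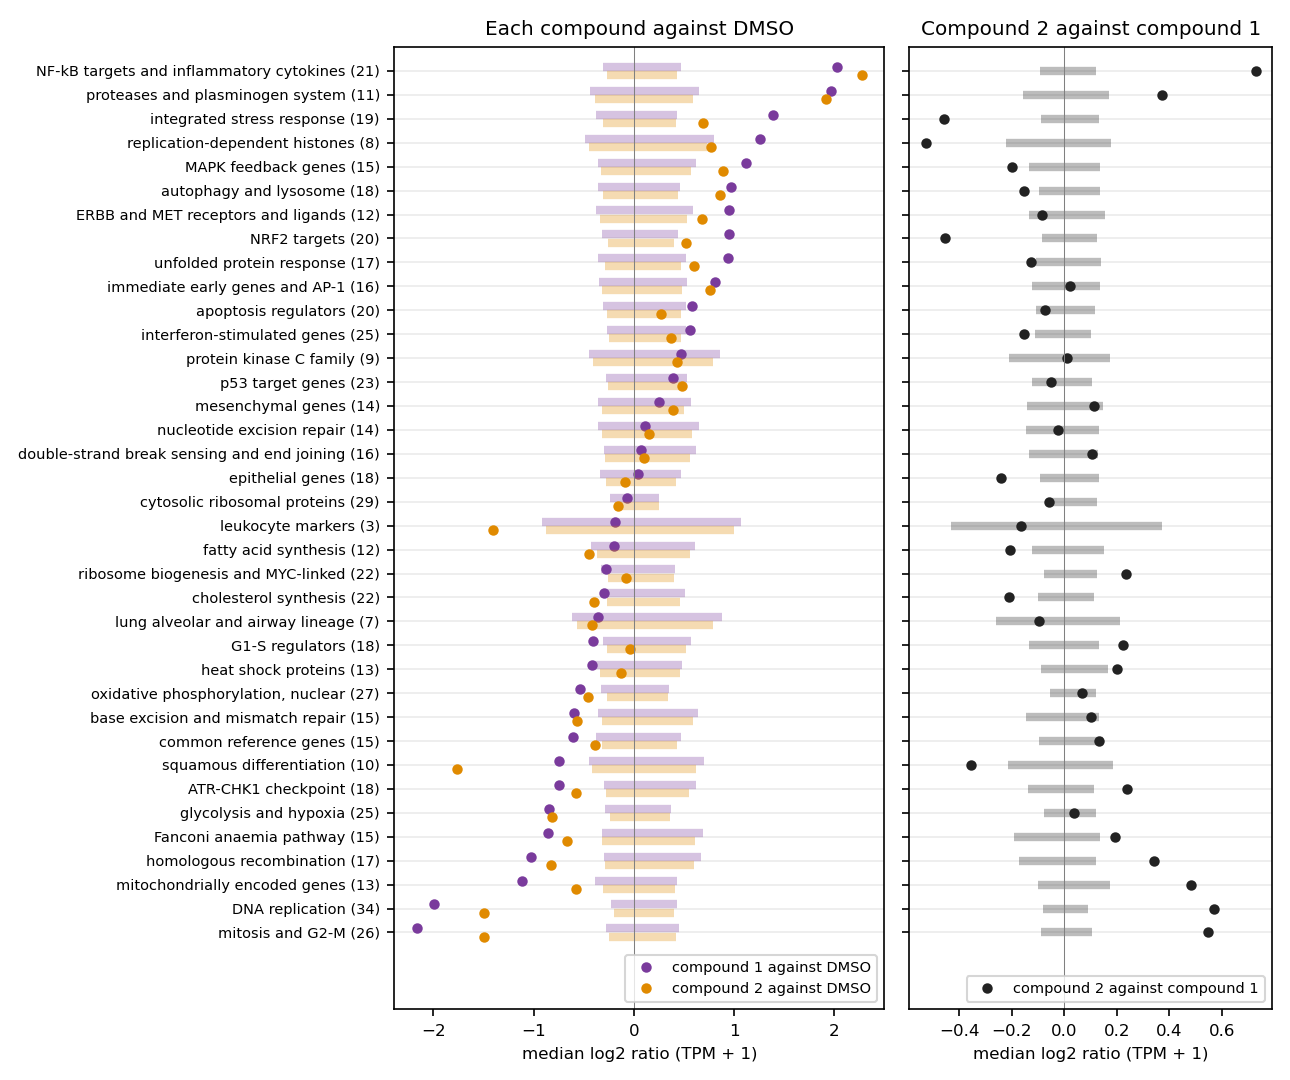
Median log2 ratio of TPM + 1 of each gene list with at least 3 measured members (number in parentheses), for each compound against DMSO (left, purple and orange points) and for compound 2 against compound 1 (right, black points), with 1 library per group. Bars span the central 95% of 10000 random lists of matched size and mean TPM, and the mitosis and DNA replication medians after compound 1 stand lowest on the left, at -2.17 and -2.0.

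Both compounds gave largely the same pattern against the shared DMSO library. Genes past 2-fold in the same direction with both numbered 1927, of 2946 past 2-fold with at least 1 compound, and none passed 2-fold in opposite directions. These were 1299 higher and 628 lower genes. Independent lists would share 216 and 61.6, and simulated unchanged libraries against a shared simulated control shared 12.8 and 13.9 on average. Across genes, which are not independent replicates, Pearson's r of the log2 ratios was 0.94, against 0.50 in the simulations, where equal noise fixes it. The covariance was 0.710 against a simulated 0.0462, a difference of 0.664. The sign was the same for 90% of genes (66.6% simulated). With a single DMSO library the control could not be split. The simulations gave the control no more noise than the compound libraries, so part or all of the excess may come from the shared control.

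**Figure D2:**
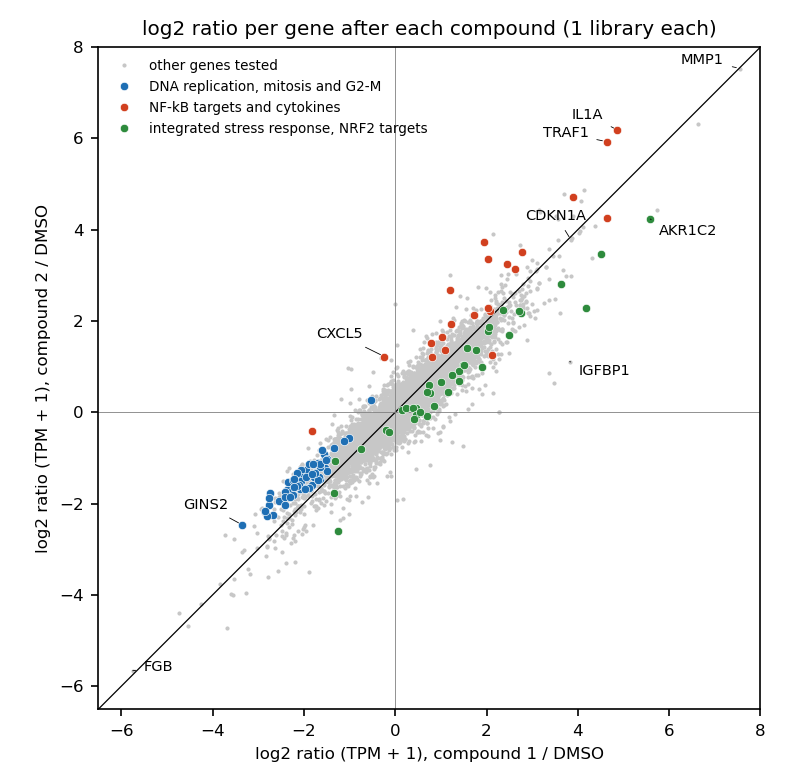
log2 ratio of TPM + 1 against DMSO for each gene after compound 1 (horizontal axis) and compound 2 (vertical axis), 1 library per group, with the diagonal of equal ratios. Blue points are DNA replication and mitosis genes, red points NF-kB targets and cytokines, and green points integrated stress response genes and NRF2 targets. Most red points, such as IL1A (4.87 and 6.18), lie above the diagonal, and most green points, such as AKR1C2 (5.59 and 4.23), below it.

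The third comparison asked where the compounds differed at 5 μM and 24 h. The median of the NF-kB and cytokine list was higher after compound 2 than after compound 1, and the medians of the integrated stress response and NRF2 target lists were lower, while most members of each differed by less than 2-fold. IL6 was at 15.9 TPM after compound 1 and 57.6 TPM after compound 2 (log2 ratio 1.79), CXCL3 at 40.9 and 116 TPM (1.48), CXCL5 at 521 and 1436 TPM (1.46) and IL1A at 197 and 493 TPM (1.32). IGFBP1, an insulin-like growth factor binding protein gene (ENSG00000146678, chromosome 7, 45888357 to 45893668), was at 458 TPM after compound 1 and 69.0 TPM after compound 2 (-2.71), against 31.5 TPM in the DMSO library. Only 34 of 11600 genes were at least 2-fold higher and 64 lower, with a median log2 ratio of -0.01. A pseudocount of 5 gave 13 and 16, and a pseudocount of 0.1 gave 107 and 152. With 1 library for each compound, the difference between the compounds has no interval, and a small difference does not show that they act alike.

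The other genes with the largest ratios in favour of compound 2 were S100A3 (2.00), ARHGAP31 (1.80), PPIP5K1 (1.48), XPNPEP3 (1.45) and POMT2 (1.42). SERPINB2, which encodes a plasminogen activator inhibitor and was listed at 0 in the DMSO library, was at 3.44 and 13.9 TPM (1.75). MAGED4B (1.91), EIF3CL (1.5) and NPIPA7 (1.47) also ranked there, but share 93.3%, 65.5% and 90.4% of their 31-mers with other genes. The closest were MAGED4, EIF3C and NPIPA8. In the other direction stood the kinase gene WNK4 (-2.83), AMMECR1L (-2.52), C11orf86 (-2.22), AKR1C1 (-1.89), CYP4F3 (-1.44), AGR2 (-1.38) and AKR1C2 (-1.35). IFNAR2-IL10RB (-1.70), CRAMP1 (-1.49), MAGED4 (-1.41) and H4C15 (-1.38) had over 50% of their 31-mers in other genes, at 54.7%, 52.9%, 100% and 91.2%.

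In the NF-kB and cytokine list 7 of 21 genes were at least 2-fold higher after compound 2 than after compound 1 and none lower (median 0.73). They were IL6, CXCL3, CXCL5, CXCL1 (1.41), the GM-CSF gene CSF2 (1.33), IL1A and TRAF1 (1.30). CXCL1 and CXCL5 did not exceed their DMSO level after compound 1. CXCL1 also stayed below that level after compound 2, at 82.0 TPM against 110 TPM in the DMSO library (-0.42). Proteases had 2 of 11 higher (median 0.37, and 0.26 without the 3 genes listed at 0). All 34 replication genes and all 26 mitosis genes had ratios above 0, with none past 2-fold (medians 0.57 and 0.55), so both lists were nearer to the DMSO level after compound 2. RRM2 was at 44.3 TPM after compound 1 and 87.3 TPM after compound 2 (0.96). Mitochondrially encoded genes (0.48), homologous recombination (0.34), the ATR-CHK1 checkpoint (0.24), ribosome biogenesis (0.23), G1-S regulators (0.22), heat shock proteins (0.20) and the Fanconi anaemia pathway (0.19) also lay above the random lists, with no member past 2-fold.

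NRF2 targets were lower after compound 2 for all 20 measured genes, 4 of them by at least 2-fold (median -0.45). The 4 were AKR1C1, AKR1C2, AKR1B10 (-1.34) and SLC7A11 (-1.04). The integrated stress response had 18 of 19 genes below 0 and 1 past 2-fold (median -0.46), with TRIB3 at -0.91, CTH at -0.82 and DDIT3, which encodes CHOP, at -0.80. Histones (-0.53), squamous differentiation (-0.36), epithelial genes (-0.24), cholesterol synthesis (-0.21), fatty acid synthesis (-0.21), MAPK feedback (-0.20), autophagy and lysosome (-0.16), interferon-stimulated genes (-0.15), the unfolded protein response (-0.13) and cytosolic ribosomal proteins (-0.06) also lay below the random lists. The members past 2-fold in these were KRT16 (-1.21), INSIG1 (-1.06), GABARAPL1 (-1.09) and DNAJB9 (-1.02). The unfolded protein response median lay inside under 3 of the other settings, and that of ribosomal proteins inside unmatched random lists. The remaining medians lay inside, namely double-strand break sensing (0.11), base excision and mismatch repair (0.10), nucleotide excision repair (-0.02), p53 targets (-0.05), apoptosis (-0.07), immediate early genes (0.02), ERBB and MET (-0.08), protein kinase C (0.01), glycolysis and hypoxia (0.04), mesenchymal (0.11), lung (-0.10), leukocyte (-0.17), nuclear oxidative phosphorylation (0.07) and reference genes (0.13). In these lists GDF15, a p53 target, and the lysozyme gene LYZ were lower by more than 2-fold (-1.15 and -1.22). In all, 23 of 37 lists lay outside. Of the 1927 genes past 2-fold with both compounds, 1295 (67.2%) lay further from the DMSO level after compound 1.

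**Figure D3:**
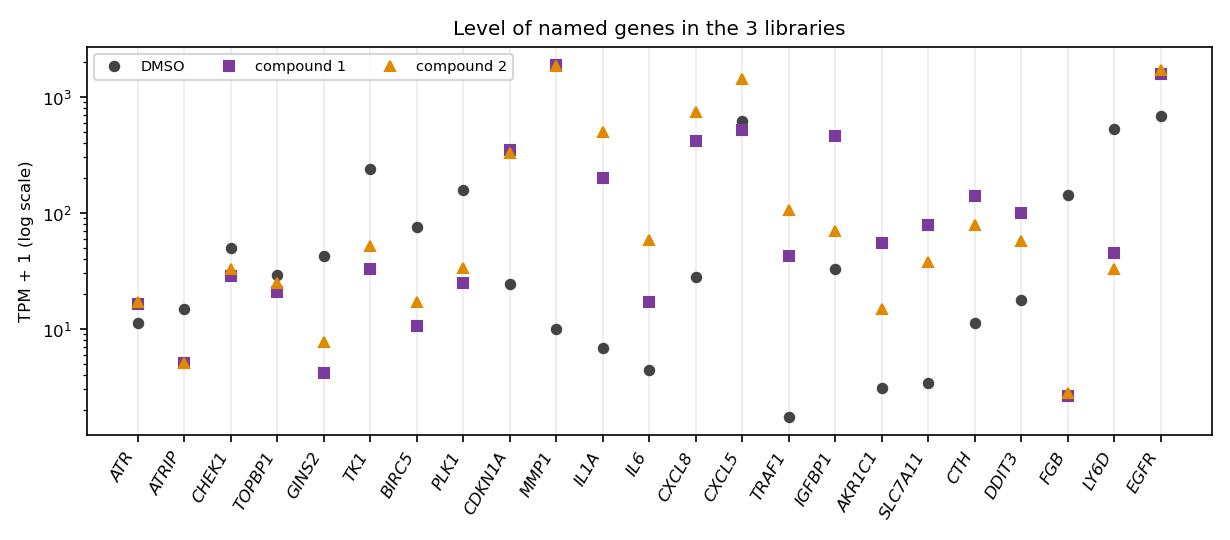
TPM + 1 of named genes in the DMSO (circles), compound 1 (squares) and compound 2 (triangles) libraries on a log axis, 1 library per group. The replication genes GINS2 and TK1 are highest in DMSO, IL1A and IL6 highest after compound 2, and IGFBP1 and AKR1C1 highest after compound 1.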

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

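The rule for the genes given here and the tests of scaling, of the DMSO library, of RNA recovery and of shared reads were chosen only after the results were seen, while the tests of the length and GC trend and of GC content were written before theirs.

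Among named genes, 10 had log2 ratios of at least 0.2 in opposite directions after the compounds, each in 1 library per compound, and the difference was not tested. CXCL5 was at 615 TPM in the DMSO library, 521 TPM after compound 1 and 1436 TPM after compound 2, a log2 ratio of 1.46 between the compounds. The sterol regulator gene INSIG1 was at 41.8, 56.0 and 26.3 TPM (-1.06). PPIP5K1 was at 21.7, 10.6 and 31.4 TPM (1.48). S100A3 was at 2.81, 0.87 and 6.5 TPM (2.00), and C11orf86 at 2.56, 8.99 and 1.15 TPM (-2.22), both under 10 TPM in all 3 libraries. EIF3CL (1.5), NPIPA7 (1.47) and H4C15 (-1.38) had over 50% of their 31-mers in other genes. MAGED4 (-1.41) and MAGED4B (1.91) had opposite signs.

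MAGED4 was at 8.67, 18.0 and 6.13 TPM in the DMSO, compound 1 and compound 2 libraries, and MAGED4B at 5.44, 2.31 and 11.4 TPM. Of the 31-mers of MAGED4B, 93.3% also occur in other genes, with MAGED4 the closest. The summed value of both genes was 20.3 TPM after compound 1 and 17.5 TPM after compound 2, a log2 ratio of -0.20, so the opposite directions may come from how reads shared by the pair were divided. No biological explanation for the split was tested.

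Replication and mitosis genes were lower after both compounds, with a median over 60 genes of -2.06 after compound 1 and -1.49 after compound 2. With the trend in transcript length and GC content subtracted the medians were -2.11 and -1.53, which argues against the trend as the whole cause. Under median-of-ratios and upper-quartile scaling they were -2.17 and -1.58, and -2.16 and -1.61. The median-of-ratios factors lay between 0.958 and 1.03, so such rescaling could move the medians only slightly. It shows that the fall does not depend on the choice among these scalings, and no more. The value nearest 0 under any rescaling, -1.49, came from rescaling to a fixed sum, which the libraries already had and so tests nothing. An unusual DMSO library stays open, because the series has 1 DMSO library. A lower share of cycling cells was not tested.

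Genes with longer transcripts had higher ratios after both compounds, with a Spearman correlation of 0.30 and 0.32 across 11542 genes. The correlation with GC content was -0.39 in both comparisons with DMSO, and given GC content the partial correlation with length was positive in both (0.209, with 0.189 to 0.226 as the 95% range over resampled genes, after compound 1, and 0.231, with 0.211 to 0.247, after compound 2). The bounds set beforehand were under 0.1 if GC content were the cause and over 0.2 if not. Given length, the partial correlation with GC content was -0.33 in both comparisons, larger in size than that with length given GC content. Both ranges for length, added after the values were seen, lie above 0.1, although the range for compound 1 includes 0.2. They rest on genes of the same libraries, which are not independent, and do not measure variation between libraries. Within these libraries the values argue against GC content, as measured on the longest transcript, as the whole cause of the length trend. Length-dependent recovery of RNA that differs between libraries could give the same trend and cannot be told apart from an effect of the compounds, since there is 1 DMSO library.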

How the results depend on the processing

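The subtraction of the length and GC trend and the protease list without its members at 0 in the DMSO library were chosen after seeing the data, and the other settings were planned. Genes higher after compound 1 numbered 985 at a pseudocount of 5, 3277 at a fold threshold of 1.5, 569 at a threshold of 3 and 976 with the trend subtracted, against 1707. Genes lower after compound 1 numbered 560, 2084 and 332 at the first 3 of these settings, against 939. Genes higher after compound 2 numbered 804, 2970, 428 and 790, against 1467, and genes lower 431, 1833 and 261, against 761. Genes past 2-fold in the same direction with both numbered 1080, 4206 and 568, against 1927. Between the compounds, genes higher after compound 2 numbered 107 at a pseudocount of 0.1, 13 at 5, 22 at a mean of at least 5 TPM, 300 at 1.5-fold and 6 at 3-fold, against 34. Genes lower numbered 152, 16, 31, 364 and 14, against 64. The fold thresholds, the pseudocounts and the filter change these counts by construction; for the trend, which is also centred at 0 by construction, the cause was not tested. The squamous differentiation median after compound 1 reversed to 0.0778 at a mean of at least 5 TPM, where fewer members enter. Gene list medians were counted once per comparison and alternative setting. Of these, 1179 kept their call against the random lists, 22 came to lie inside and 19 outside. Some of the 1179 lay inside and changed sign, such as double-strand break sensing after compound 1, from 0.07 to as low as -0.26. Fixed-sum, median-of-ratios and upper-quartile scaling each kept all 111 calls. A constant per library moves a list and its random lists nearly together, so these could hardly change. Of the values of named genes, 4678 kept their side of 2-fold and 251 no longer passed it, mostly at a pseudocount of 5 or with the trend subtracted. The correlation of both comparisons lay between 0.93 and 0.95. Rescaling to a sum of 1000000 tests nothing, since the libraries already had that sum after rounding. It changed the genes higher after compound 2 from 1467 to 1466. No paired analysis was possible because each group had 1 library. Depth limits genes near 1 TPM, which rest on about 16.3 to 18.8 reads per 2-kb transcript.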

Other observations

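The regions and genes here were chosen after their values were seen, and no explanation was tested. In windows of 11 neighbouring protein-coding genes, the highest median level of 19425 windows lay on chromosome 7 from 54752250 to 56063989 (GRCh38), tied with the next window along. It reached from SEC61G and EGFR, at its start, to CCT6A. The window centred on EGFR ranked only 4569, and that centred on SEC61G 2466. In the DMSO library SEC61G, a translocon subunit gene next to EGFR, was at 7674 TPM, the rank of 5 among all genes. VOPP1 was at 2045 TPM, CCT6A at 1703 TPM, EGFR at 680 TPM and LANCL2 at 563 TPM, while SEPTIN14 in the same window was listed at 0. SEC61G was at 10712 TPM after compound 1 and 8895 TPM after compound 2.

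CDK4, the kinase gene of the G1 phase on chromosome 12 (57747727 to 57756013), was at 5995 TPM in the DMSO library, a rank of 10 among all genes. It was at 2758 TPM after compound 1 (log2 ratio -1.12) and 2973 TPM after compound 2 (-1.01). The window centred on CDK4 ranked 5024, with 3 of 11 genes at a mean of at least 50 TPM. A pair of nearby genes was also high, with OS9 at 1859 TPM and PIP4K2C at 926 TPM in the DMSO library, 2312 and 1245 TPM after compound 1, and 2128 and 1287 TPM after compound 2. Some nearby genes lay between, with MARS1 at 245 TPM, DCTN2 at 222 TPM, TSPAN31, which overlaps CDK4, at 149 TPM and TSFM at 103 TPM in the DMSO library. Others there were low, with AGAP2 at 2.26 TPM, CYP27B1 at 0.878 TPM, DTX3 at 0.711 TPM and ARHGEF25 at 0.412 TPM in the DMSO library.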
